A study of Bos taurus with 10 samples.

How the data were processed

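Liver RNA of Holstein cows, a dairy breed of Bos taurus, sampled 2 weeks before expected calving was profiled in 10 libraries by 3' mRNA sequencing, which reads the end of each transcript next to the poly(A) tail and so gives about 1 read per transcript molecule sampled, whatever the transcript's length. Per the labels, 5 libraries came from over-conditioned and 5 from normal-conditioned animals. Libraries were made with the QuantSeq forward kit and sequenced as single reads of 75 bases on an Illumina NextSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt 1.18, STAR 2.6.0c and RSEM 1.3.1 and the cattle genome builds ARS-UCD1.2 and bosTau9, without giving their roles or order.

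The authors deposited whole-number counts per Ensembl gene ID, 27607 IDs in 10 libraries, with no normalisation. All values are whole, although RSEM, which is named in the submitters' processing notes, usually gives estimates that are not. They were analysed as counts, and rounded estimates would enter the tests in the same form. How reads that match several genes were treated is not given in the sources used here. The labels do not say in so many words that each library is a separate animal. The p-values therefore weigh differences against the spread between these samples, which may not be the spread between animals.

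The file does not pair its IDs with gene symbols, and 0 of its IDs matched the gene table used here. No gene is therefore named, placed on a chromosome or given a function. For the same reason the 45 pathway and cell type lists fixed before the data were examined were not tested. The rule for named genes, fixed at the same time, chose genes by symbol and allowed at most 2 higher and 2 lower genes to be given by ID where no symbol exists. It set no order for such IDs. The order by smallest p in each direction was chosen after the p-values were seen, and these genes are given as values, not as changes.

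Genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 9162 of the 15973 IDs with any count. Counts were scaled by TMM and compared with the quasi-likelihood F-test with Benjamini-Hochberg adjustment at a threshold of 0.05. Folds are over-conditioned over normal-conditioned. Standard errors were taken from the fold and the F statistic, and the 95% intervals built on them are approximate. Log2 CPM for principal components and distances used a prior count of 2. Whole-library measures were compared by exact two-sided permutation over all 252 regroupings, in SciPy 1.17.1 under Python 3.11.15, with Benjamini-Hochberg adjustment over the 10 such comparisons made. The distances between libraries were compared over the same regroupings, by the share of variance between conditions. Alternatives used DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0 in R 4.3.3, other scalings and filters, a block for the replicate number, 1 surrogate variable, and leaving out each library in turn.

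The edgeR comparison, its alternatives, the total counts and the share of the 10 most abundant genes were planned. Chosen after the edgeR result was seen were the count at an unadjusted p under 0.05, the counts of separated genes and of narrow intervals, the other 8 whole-library comparisons, the standing of single libraries, the search for identical rows, the genes with wide ranges, and the adjustments for the letters in the library names. A count of genes near 0 in some libraries was also tried at several thresholds and is not reported.

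The tests were tried on simulated data with the means, spread and library sizes of this comparison and 200 changed genes among 9162, in 5 sets. At adjusted p under 0.05, edgeR recovered 10% of 1.5-fold, 60% of 2-fold, 89.2% of 3-fold and 98.4% of 4-fold changes, and 4.59% of its calls were false. DESeq2 recovered 19.6%, 66.4%, 91.2% and 99.2%, and 9.44% of its calls were false. These shares hold for 200 changed genes per set, with each gene drawn independently of the others. Fewer changed genes were not simulated, so the shares do not show that changes of these sizes are absent when few or no genes are called. Total counts per library ran from 3892292 to 6737548.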

Results

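The liver transcriptome was measured in 5 libraries labelled over-conditioned, from dairy cows carrying excess body fat, and 5 labelled normal-conditioned, all sampled 2 weeks before expected calving. In the over-conditioned group, total counts were 4341566, 3892292, 6275707, 5203632 and 6737548 for replicates 1 to 5. In the normal-conditioned group they were 6491675, 6189459, 4874244, 5957752 and 5677765. The mean total was 5290149 ± 1217332 (SD, n = 5) in over-conditioned and 5838179 ± 616372 (SD, n = 5) in normal-conditioned libraries, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.405). Between 12310 and 13037 genes had a count in each library.

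A few genes made up a large part of every library. The 10 most abundant genes held 29.1% ± 2.25 of counts in over-conditioned and 28.8% ± 1.49 in normal-conditioned libraries (SD, n = 5 each), which did not differ by more than the spread between libraries (exact permutation test, two-sided, p = 0.778). The single most abundant gene held 7.46% ± 0.869 of counts in over-conditioned and 9.67% ± 1.48 in normal-conditioned libraries (SD, n = 5 each). Its exact permutation p was 0.0238 before and 0.198 after adjustment over the 10 whole-library comparisons, so this difference did not pass the adjusted threshold.

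The first question was whether libraries of one condition resembled each other more than those of the other. Principal components 1, 2 and 3 held 19.8%, 14.7% and 12.9% of the variance in log2 CPM. On component 1 over-conditioned replicate 2 lay at 45.4, against scores from −16.0 to 13.4 in the other libraries. The condition accounted for 14.2% of the variance between libraries, where 11.1% is the mean over all regroupings (exact permutation p = 0.0397, adjusted p = 0.198). The unadjusted p was over 0.05 when any one of 6 of the 10 libraries was left out. The mean distance within groups was 60.6 in over-conditioned and 56.4 in normal-conditioned libraries, and 60.4 between groups. Without over-conditioned replicate 2 the over-conditioned value was 56.3.

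**Figure D1:**
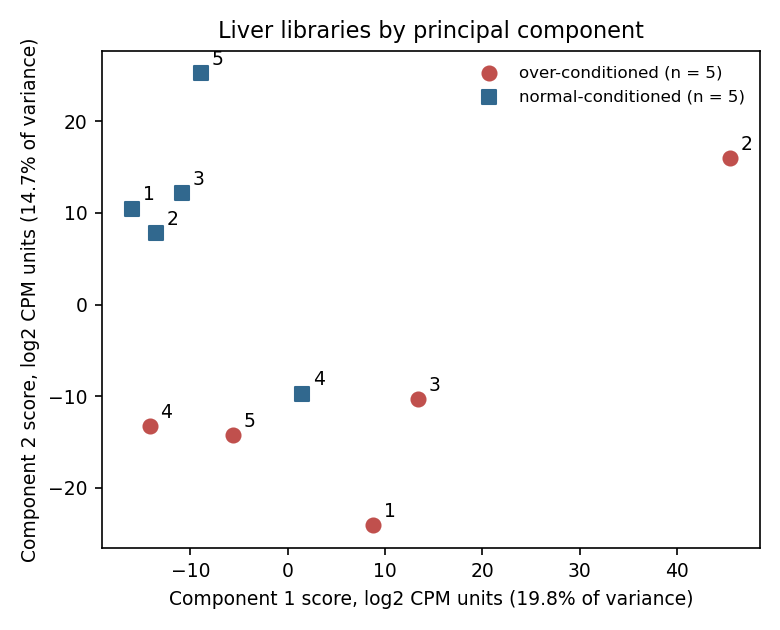
Principal component scores of the 10 liver libraries, in log2 CPM units, with over-conditioned libraries as circles, normal-conditioned libraries as squares and replicate numbers beside the points. Over-conditioned replicate 2 lies at 45.4 on component 1, and normal-conditioned replicate 4 lies among the over-conditioned libraries on component 2.

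The main comparison asked which genes differed in level between over-conditioned and normal-conditioned libraries. No gene passed: 0 of 9162 genes tested with edgeR's quasi-likelihood test had an adjusted p under 0.05, and the smallest adjusted p was 0.400. At an unadjusted p under 0.05 there were 692 genes, 381 higher and 311 lower in over-conditioned libraries, where 458 are expected with no difference. Limma-voom also called 0 genes, while DESeq2 called 21, of which 10 were higher and 11 lower. All 21 had an unadjusted p under 0.05 in edgeR, which tests the same counts, so this is no independent support. In 124 genes, 60 higher and 64 lower, the 2 groups did not overlap, which is 1.35% of the genes tested against the 0.794% that chance gives.

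**Figure D2:**
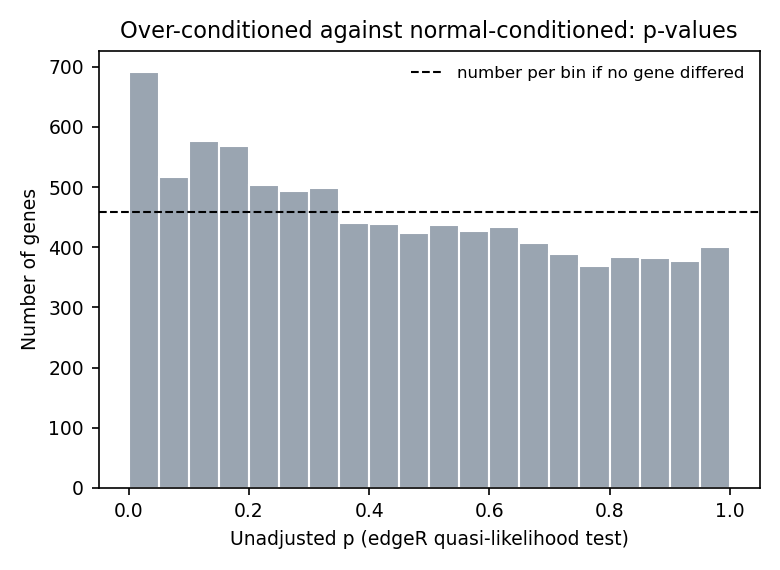
Unadjusted p-values of the 9162 genes from edgeR's quasi-likelihood test, over-conditioned against normal-conditioned libraries, as the number of genes per bin. The dashed line marks the number expected in each bin if no gene differed, and the first bin holds 692 genes against 458.

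The 2 genes with the smallest p in each direction are given as values, since none passed the adjusted threshold in edgeR (adjusted p = 0.400 for each). All 4 were among the genes called by DESeq2. ENSBTAG00000005373 stood at 34.98 ± 2.53 CPM in over-conditioned and 55.8 ± 4.15 CPM in normal-conditioned libraries (SD, n = 5 each), a log2 fold of −0.67 (SE 0.120). ENSBTAG00000040413 stood at 232 ± 36.7 and 386 ± 48.4 CPM in the same order, a log2 fold of −0.73 (SE 0.147). In both, every over-conditioned library lay below every normal-conditioned one. ENSBTAG00000020391 stood at 18.3 ± 2.95 CPM in over-conditioned and 8.60 ± 2.32 CPM in normal-conditioned libraries, a log2 fold of 1.08 (SE 0.208), without overlap between the groups. ENSBTAG00000055034 stood at 8.70 ± 6.48 and 1.101 ± 0.825 CPM, a log2 fold of 2.93 (SE 0.603). This gene rested on 1 to 112 counts per library, and its groups overlapped, with 1.72 CPM in over-conditioned replicate 4 and 2.14 CPM in normal-conditioned replicate 4.

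**Figure D3:**
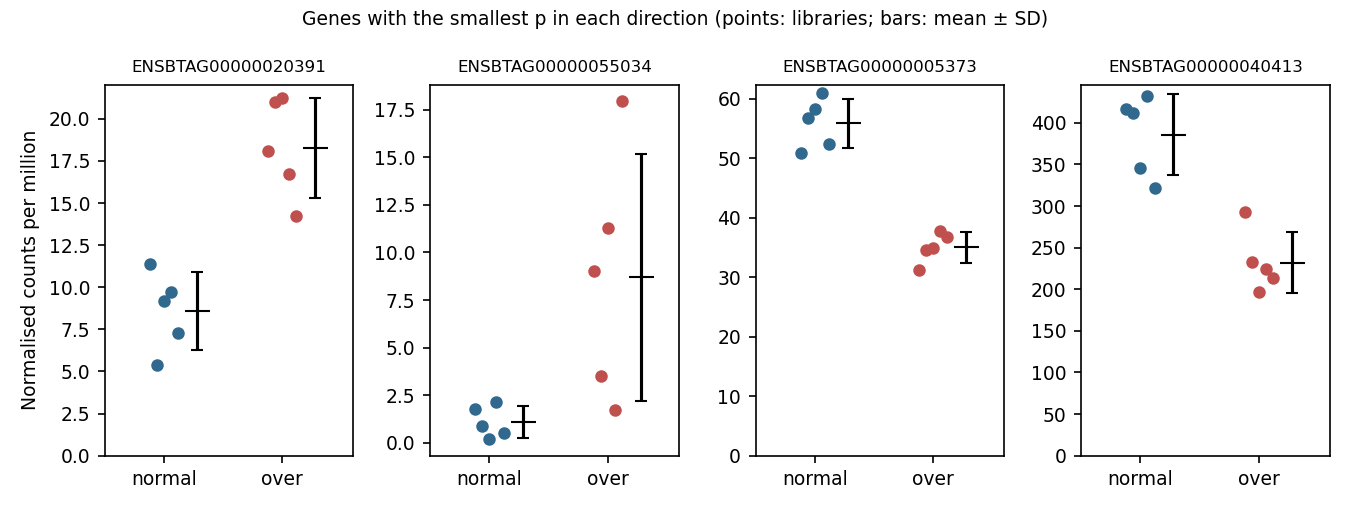
Normalised counts (CPM) of the 2 higher and the 2 lower genes with the smallest p, with 1 point per library and the mean ± SD beside each group of 5. ENSBTAG00000005373 lay between 31.1 and 37.8 CPM in over-conditioned and between 50.9 and 60.9 CPM in normal-conditioned libraries.

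The precision of the comparison followed the level of the gene. The biological coefficient of variation was 24.1%, and the median standard error of a log2 fold was 0.21. For 7539 genes, 82.3% of those tested, the approximate 95% interval of the fold lay within 2-fold in either direction. This share was 65.8% among the 3809 genes under 10 CPM, 93.9% among the 4331 genes from 10 to 100 CPM and 94.6% among the 1022 genes at 100 CPM or more. Intervals within 1.5-fold were reached by 3673 genes, or 40.1%.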

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

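The tests of depth and of regrouped libraries, and the block for the letters of the library names, were chosen after the results they bear on were seen. Over-conditioned replicate 2 lay far from its group in its mean rank correlation with the other libraries, 0.936 against 0.950 to 0.954 in the other over-conditioned libraries. It was the 1 such library among 28 groups of values examined in this way, where chance gives about 1 in 20, or 1.4. These groups come from the same libraries and their measures overlap, so this count does not decide whether chance is enough. Over-conditioned replicate 2 was also the shallowest library, with 3892292 counts. Lower depth alone is argued against: when all libraries were thinned to that total, the gap to the next lowest library was 0.961 of its size (SD 0.0306 over 20 thinnings), and it was lowest in 20 of 20. Chance and a difference in this sample or its RNA stay open, and no biological explanation was tested.

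Chance was not excluded for the number of genes that differ between the conditions. Among 100 splits of the 10 libraries into 5 and 5, the real one included, 8 gave at least 692 genes at an unadjusted p under 0.05 in edgeR, and the highest other split gave 1126. DESeq2 was fitted to each split on the genes that passed edgeR's filter, a separate fit from the one that called 21; it called 23 for the real split, 9 of 100 gave at least as many, and the highest other split gave 121. For edgeR calls the real count of 0 fixes the outcome, 100 of 100 with 5 as the highest other, so it says nothing about chance. DESeq2 counts of several times the real one may point to a structure of the samples, but none was tested for beyond the letters of the library names. The split with 121 had 0 edgeR calls and 1123 genes at an unadjusted p under 0.05. One with 94 DESeq2 calls had 5 edgeR calls and 1126 such genes. This last split differs from the real one by a single exchange of libraries, as do those with 65, 52 and 42 DESeq2 calls. Such splits keep most of the real grouping, and the other splits that reached either real count differ by more.

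The split with 121 calls parted the libraries by the letter in their names, A to C against D to H, whose meaning the labels do not give. Since that division was taken from the split that called most genes, its count is selected and is no evidence that the letters matter. With the division as a block, 641 genes had an unadjusted p under 0.05 between the conditions in edgeR. With the letter's position as a covariate there were 539, against 692 without either. DESeq2, on the genes that passed edgeR's filter, called 23 between the conditions with the block and 23 without it. Whether the letters account for part of the excess cannot be told apart from chance. Distance in expression, after removing the group means, and distance between letters had a Mantel r of 0.0684 over all 45 pairs of libraries (permutation p = 0.310, one-sided, 100000 permutations), the form set beforehand, and of −0.135 over the 20 pairs within groups (exact permutation p = 0.382, one-sided), a form chosen later and computed first. Both lay on the same side of the middle of their permutations, and neither decides. The 641 genes lay on the side set beforehand as evidence against the letters. The count without a block ran from 518 to 851 without single libraries. That range comes from other sets of samples, so it does not measure the error of a change of model on the same libraries. No such error was computed. The count of 641 was read as undecided only after the value was seen. Over-conditioning itself and the order of the numbers in the library names both stay open as reasons for the excess. Over-conditioned libraries hold the lowest of these numbers, except that over-conditioned replicate 5 comes just after normal-conditioned replicate 1. The design can therefore hardly tell them apart, for this excess or for any other comparison between the conditions.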

How the results depend on the processing

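The results at an unadjusted p, the variance between conditions, the share of the most abundant gene, the letters and the identical rows were examined only after the planned results were seen. The count of 0 genes in edgeR held in 22 of 24 alternatives. The exceptions were DESeq2 with 21 genes, and leaving out single libraries, which gave 0 to 1 genes; the 1 gene appeared without normal-conditioned replicate 1, where it stood at 12.8 CPM. The cause of the DESeq2 difference was not tested. The count at an unadjusted p under 0.05 ran from 518 to 851 when single libraries were left out. The 4 genes given by ID kept their direction in all 95 fits made for them and passed the threshold in 4, all with DESeq2. They were chosen by smallest p in these same libraries, which the fits reuse, so the kept direction is no independent support. The difference in the share of the 10 most abundant genes, 0.355 percentage points, ran from −0.178 to 1.23 without single libraries and turned negative without normal-conditioned replicate 5 or over-conditioned replicate 3 or 5; the cause was not tested. The variance between conditions ran from 14.4% to 17.1% without single libraries, with p over 0.05 in 6 of 10, where fewer samples enter. With fewer samples the mean share over regroupings is also higher, so these shares cannot be set directly against the 14.2% of all libraries. The difference in the share of the most abundant gene ran from −2.66 to −1.67 percentage points, with an unadjusted exact permutation p of 0.0159 to 0.0476. With the replicate block, 0 genes were called and 502 had an unadjusted p under 0.05. The replicate numbers showed no pairing in expression: deviations of same-numbered libraries correlated at −0.218 to −0.00016, and 0 of 10 libraries were closest to their own number. A pairing that leaves no shared expression profile is not excluded by this. The tests of the 45 gene lists and all their alternatives were not run, for want of gene symbols. Intervals were widest for genes under 10 CPM; whether depth or spread between samples sets this was not tested.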

Other observations

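These values were all chosen after the data were seen. Among 1022 genes at 100 CPM or more, the median range between the lowest and highest library was 1.79-fold, and 5 genes ranged over more than 32-fold. ENSBTAG00000006354 ran from 14.8 CPM in normal-conditioned replicate 2 to 4743 CPM in over-conditioned replicate 1, with 296 to 4743 CPM in over-conditioned and 14.8 to 2000 CPM in normal-conditioned libraries (edgeR adjusted p = 0.687). ENSBTAG00000002069 stood at 15.3 CPM in normal-conditioned replicate 1 and at 1015 to 2072 CPM in the other 9 libraries. By group it ran from 1397 to 2072 CPM in over-conditioned and from 15.3 to 1295 CPM in normal-conditioned libraries (edgeR adjusted p = 0.783). ENSBTAG00000019588 had 0 counts of 5957752 in normal-conditioned replicate 4, which allows up to 0.495 CPM, and 277 CPM in normal-conditioned replicate 1, at least 560-fold higher. The floor of 3 counts covers counting error only.

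Genes that follow these across the libraries were searched for in 2 cases, with a negative outcome. At an absolute Pearson r over 0.9, ENSBTAG00000019588 had 4 such genes and ENSBTAG00000006354 had 6, where the median of 200 other abundant genes was 6.

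In 7 pairs of IDs, 14 in all, the counts were identical in every library at a total of 100 or more, with totals up to 1762. Coincidence is argued against, since 100 Poisson redraws of the table gave 0 such repeats. Reads shared between near-identical copies are a candidate explanation for these 7 pairs, but the redraws do not separate them from 1 locus entered under 2 IDs. All 14 IDs were tested and 4 had an unadjusted p under 0.05, so each pair enters those totals under both IDs. No biological explanation was tested.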
